A study of Homo sapiens with 18 samples.

How the data were processed

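RNA was measured in MCF7, an established estrogen receptor-positive human breast cancer cell line. Cells were deprived of hormone for 3 days and then given estradiol (E2) at 10 nM or the vehicle, 0.1% ethanol, for 1 h. Total RNA, polysome-associated RNA and monosome-associated RNA were profiled in each treatment, which gives 6 groups of 3 biological replicates and 18 arrays. Per the labels' protocols, ribosome-bound RNA was recovered from sucrose gradient fractions by precipitation, total RNA was extracted with Trizol, and both were cleaned on columns with DNase. The arrays were Affymetrix Human Gene ST arrays with an input of 300 ng of RNA, per the labels. The labels state that polysome RNA was taken from the same cells as total RNA, and they give no hybridisation batch or date. Arrays are named here by group and replicate number.

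The deposited values are intensity values on a linear scale, 1 per probe set and array, for 33250 probe sets. Per the submitters' processing notes they came from Affymetrix Power Tools; the version is not given, and the background and summary method are not given in the sources used here. Array medians lay between 79.1 and 98.1, and between 16.5% and 21.7% of the probe sets of an array were below 16. The files hold no counts or detection calls, so the number of arrays limits the precision of each value. No scanner files were used, so the background correction and the summary of probes were taken as deposited. Every per-sample value column was used.

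Each value was transformed as log2(value + 16). Genes were named from the platform annotation supplied with the series, with symbols looked up through Entrez identifiers: 19455 probe sets had 1 symbol, 1751 had several and 12044 were not listed, which leaves them unnamed here rather than without a gene. Of the probe sets with 1 symbol, 19424 matched by Entrez identifier and 0 symbols changed. Each gene was represented by the probe set with the highest mean over the 18 arrays, which gave 18414 genes; 767 genes had more than 1 probe set. Another probe set of the gene passed in the opposite direction for 0 genes in the E2 comparisons, and for 18, 13 and 45 genes in polysome against total, monosome against total and polysome against monosome RNA. Probe sets with several or no symbols were left out of the gene counts and are reported only as numbers. The position of the probe sets on a genome build is not given with the values and is not reported.

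A linear model with 1 mean per group was fitted to all 18 arrays with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, 12 residual and 7.189 prior degrees of freedom), with no filter on level and no block. The 9 comparisons were contrasts of group means: E2 against vehicle in each of the 3 fractions, the 3 differences between those effects (interaction terms), and polysome against total, monosome against total and polysome against monosome RNA, each averaged over both treatments. Tests were two-sided, and a gene passed at a Benjamini-Hochberg adjusted p under 0.05 over all genes. In what follows, every adjusted p of a gene is from this limma fit, "SE" is the standard error of a log2 fold change in it, and n is 3 arrays per group. Intervals are 95% confidence intervals from the same fit.

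Gene lists were tested with limma's camera at its preset inter-gene correlation of 0.01, adjusted over the 17 measured lists of a comparison. Camera at an estimated correlation and fry were run beside it. Camera tests a list against the other genes, while fry tests it against no change. The comparisons, the threshold, the lists, the rule for named genes and most alternatives were set before the data were examined. The 18 lists were early estrogen-induced genes, genes reported as estrogen-repressed, immediate early genes, REST (NRSF) target genes, REST and its corepressors, ribosomal proteins and elongation factors (TOP mRNAs, whose leaders start with an oligopyrimidine tract), translation initiation factors and their regulators, ribosome biogenesis factors, mRNAs with regulatory upstream reading frames, secreted and membrane proteins made at the endoplasmic reticulum (ER), nuclear-retained long noncoding RNAs, replication-dependent histone mRNAs, G1/S and S phase genes, heat shock and unfolded protein genes, luminal breast epithelial markers, markers of other cell types (basal, stromal and immune), small noncoding RNA genes, and mitochondrially encoded genes. None of the 13 mitochondrially encoded genes had a probe set of its own, so that list has 0 measured members and gives no result. A gene may stand on more than 1 list; KLF4, for example, is on both the estrogen-repressed and the immediate early list. Counts "adjusted over the list alone" used the members' p values only.

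Named genes followed a rule. For E2 against vehicle, these were the 15 largest rises and 10 largest falls among genes that passed and whose 3 E2 arrays all lay on one side of the 3 vehicle arrays. For a difference of effects, they were the 10 largest on each side among those that passed, and for fraction comparisons the 12 largest on each side with the same sign in both treatments; small noncoding RNAs were listed apart. Where fewer than 5 genes passed, the 5 with the smallest p were named as not passing. A fixed set of estrogen-responsive genes, ESR1 and REST was named whatever its values, as were up to 4 members of each list that passed with the largest changes. HES1, EFNA1, VTCN1, PIK3IP1, TRIB1, CCN2, NOP16 and IGFBP4 fall outside the rule and are named after their values were seen, as the few members of a list that passed adjusted over the list alone, and so are CA12 in total RNA and the values of named genes in comparisons that did not name them.

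The fit was tested on simulated arrays of 18414 genes with 200 genes changed, 50 per size. For E2 against vehicle in total RNA it recovered 18%, 98%, 100% and 100% of changes of 0.5, 1, 1.5 and 2 on the log2 scale. For the E2 effect in polysome against total RNA it recovered 0%, 68%, 90% and 100%, and for the E2 effect in monosome against total RNA 6%, 46%, 96% and 100%. For polysome against total RNA it recovered 64%, 100%, 100% and 100%. False calls numbered 11 of 169, 6 of 135, 9 of 133 and 16 of 198 calls in these comparisons, in the same order. A simulated shift of the TOP list in E2 polysomes was found by camera at an adjusted p of 3.76e-06, with 0 of the other lists called. The simulated noise was drawn independently for each gene and array, with the same spread of a gene in each group. These rates therefore leave out correlation between genes and spreads that differ between groups, and recovery in the real arrays may differ. They do not describe list calls in the real arrays, where other splits of the polysome arrays called up to 8 lists.

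Same-numbered arrays were checked for shared deviations from their group means. Every same-numbered pair correlated above 0.1 between E2 and vehicle total RNA (0.362, 0.174 and 0.611), between E2 and vehicle monosome RNA (0.212, 0.239 and 0.233), and between vehicle total and vehicle polysome RNA (0.118, 0.196 and 0.475), so the numbers pair these samples. The other pairs of groups did not meet this. The design without a block was kept, with the replicate number as a block among the alternatives.

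Alternatives set beforehand were quantile normalisation of the arrays again, centring of each array on its median, removal of the dimmest 30% or 50% of genes, trend and robust options in eBayes, array weights, only the compared groups in the fit, every probe set on its own, an adjusted p under 0.10, at least a 1.5-fold change, 1 treatment alone, a replicate or culture block, and leaving out each array in turn. The culture block took same-numbered arrays of a treatment as coming from the same culture. Shared cells are stated above for polysome and total RNA only, so for monosome arrays this is an assumption. After the data were seen, log offsets of 1 and 64, the scalings over the tested genes only, and leaving out both replicate 3 arrays of total RNA were added. Other splits of the arrays into groups of the same sizes were refitted: all 10 for E2 against vehicle and 100 drawn at random otherwise. Tables were handled in Python 3.11.15 with pandas 2.3.3, and figures were drawn with matplotlib 3.10.9.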

Results

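Gene expression was measured in MCF7 cells after 1 h of estradiol (E2, the main estrogen) or vehicle, in total RNA and in gradient fractions. These were polysome-associated RNA (nominally mRNA carrying several ribosomes) and monosome-associated RNA (nominally mRNA carrying a single ribosome). Each of the 6 groups held 3 biological replicates. Mean intensity per array lay between 410 and 484, and the highest intensity was 27446. Within a group, arrays correlated at 0.972 to 0.995 across genes, which are not independent replicates. The lowest of these values was in E2 total RNA, where the median gene had a standard deviation of 0.21 on the log2 scale, against 0.13 in E2 polysome RNA. In a principal component analysis the leading component held 59.5% of the variance and set monosome RNA apart from the other fractions, and the next held 21.5%. Both replicate 3 arrays of total RNA stood apart from the other total RNA arrays. Each fraction's E2 effect is a comparison within that fraction. Any difference in handling between fractions cannot be told apart from the fraction. The labels give no batch, and by their protocols total RNA was extracted with Trizol while ribosome-bound RNA was precipitated from gradient fractions. Each comparison of polysome or monosome with total RNA therefore also compares these procedures.

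**Figure D1:**
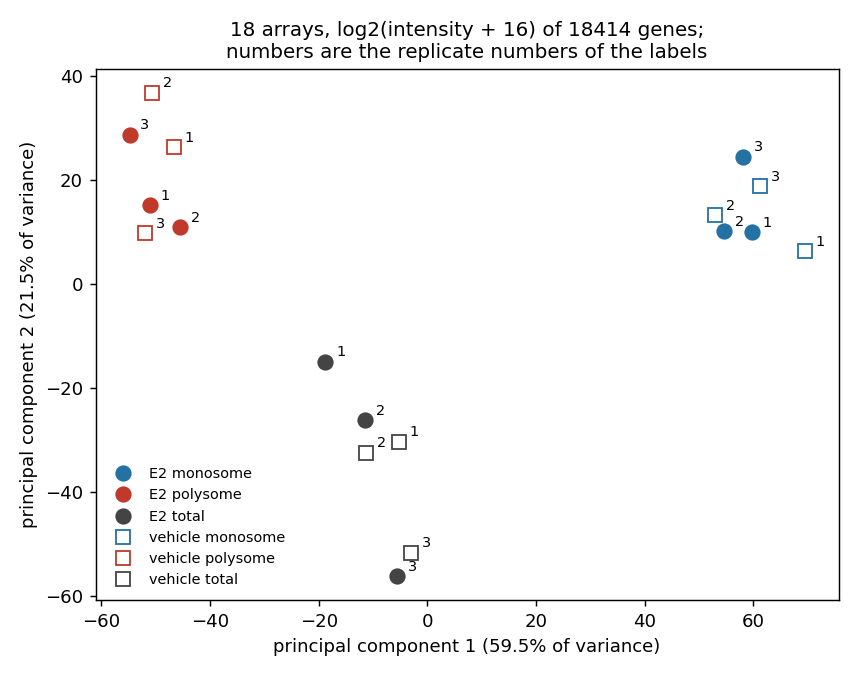
Principal components 1 and 2 of the 18 arrays, with 59.5% and 21.5% of the variance on the axes, colours for the fraction, squares for vehicle, circles for E2 and numbers for the replicate. Monosome arrays stand apart along component 1, E2 and vehicle arrays of a fraction lie together, and both replicate 3 arrays of total RNA lie at the bottom.

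The comparison of E2 with vehicle in total RNA asks which transcripts change in amount within 1 h of hormone. E2 raised a small set of genes. KCNK5, a potassium channel gene, went from an intensity of 108.6 ± 30.6 to 648.5 ± 26.8 (SD, n = 3), a log2 fold change of 2.44 (SE 0.21, adjusted p = 6.88e-06). MYC, a transcription factor that drives growth, went from 1093 ± 61.6 to 3689 ± 371 (SD, n = 3), a log2 fold change of 1.74 (SE 0.17, adjusted p = 3.33e-05). SGK1, a serum- and glucocorticoid-regulated kinase, rose by 1.39, and FOS, a leucine zipper transcription factor, by 1.18. TIPARP, an ADP-ribosyltransferase, rose by 1.18, STC2, a secreted glycoprotein, by 1.02, and XBP1, a transcription factor of the unfolded protein response, by 0.91. CD70, a ligand of the tumour necrosis factor family, fell by 1.20 on the log2 scale (SE 0.22, adjusted p = 0.0318).

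Of the 38 measured early estrogen-induced genes, 9 rose and 0 fell in total RNA, and adjusted over the list alone 17 rose. In total RNA their median log2 fold change was 0.40, and the list was shifted up (camera adjusted p = 2.36e-43, and adjusted p = 0.000147 with an estimated correlation). Besides those above, MYB, a transcription factor, rose by 1.11 and KLF10, a zinc finger factor induced by growth factors, by 0.88. Among 44 immediate early genes, 6 rose in total RNA (FOS, MYC, SGK1, KLF4, KLF10 and GADD45B) and 0 fell. Adjusted over the list alone 7 rose and 1 fell, TRIB1, which regulates protein degradation. That list was called up at an adjusted p of 0.00219, but at an adjusted p = 0.776 with an estimated correlation, and its median of 0.03 turned to -0.0004 with quantile normalisation of the tested genes. The preset call was lost without E2 total replicate 3 (median -0.045), vehicle total replicate 1, both replicate 3 arrays or the dimmest 50% of genes. KLF4, a transcription factor placed on the list of genes reported as estrogen-repressed, rose by 0.74, and no other of the 27 members of that list passed in total RNA, over all genes or adjusted over the list alone. The genes of secreted and membrane proteins, of which STC2 alone passed, as it did adjusted over the list alone, had a median of 0.05 (0.011 to 0.115 without single arrays) and were called up at an adjusted p of 0.0382, but at 0.776 with an estimated correlation. Their preset call was lost without E2 total replicate 3, vehicle total replicate 1, both replicate 3 arrays or the dimmest 50% of genes, with quantile normalisation and with a log offset of 1.

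Several textbook estrogen targets did not pass in total RNA at 1 h. The log2 fold change was 0.49 for TFF1, which encodes a secreted trefoil peptide, 0.38 for GREB1, a coregulator of the estrogen receptor, and 0.31 for PGR, the progesterone receptor gene. It was 0.25 for CCND1, which encodes cyclin D1, and 0.81 for EGR3, a zinc finger transcription factor (SE 0.32). Leaving out 1 array moved some of these values widely, from 0.14 to 0.72 for GREB1, from 0.03 to 0.70 for PGR and from 0.13 to 0.34 for CCND1. ESR1, the gene of the estrogen receptor itself, stood at -0.02 (SE 0.14; -0.13 to 0.14 without single arrays). REST, the gene of the repressor NRSF that the series title names, stood at 0.13 with a 95% confidence interval of -0.37 to 0.62 (-0.10 to 0.45 without single arrays). None of the 62 REST target genes passed in total RNA by limma, and 3 had an unadjusted p under 0.05, 1 higher and 2 lower. Their median was -0.05, and 0.0003 without vehicle total replicate 1.

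In total RNA limma called 18 genes higher and 1 lower of 18414, and 723 genes had an unadjusted p under 0.05 where chance alone gives 921. All 19 had 3 E2 arrays on one side of the 3 vehicle arrays, as did 1244 of all genes, and chance gives a share of 10%. Of 17 named genes that passed, 6 (FOS, KCNK5, MYC, SGK1, TIPARP and XBP1) passed whichever single array was left out. The other 11 did not. Without E2 total replicate 1, 10 of them were lost, without replicate 2, 9, and without replicate 3, 4. Without vehicle total replicate 1, 9 were lost, without replicate 2, 5, and without replicate 3, 11. The whole count was 7, 8 and 19 without E2 total replicates 1, 2 and 3, and 9, 15 and 6 without vehicle total replicates 1, 2 and 3. It was 3 with only these 6 arrays in the fit, 11 without both replicate 3 arrays, and 799 with array weights, in which E2 total replicate 2 alone had a weight of 6.77. With the replicate number as a block, HEY2, a transcription factor gene induced by Notch, did not pass (adjusted p = 0.057), nor did CD70 (adjusted p = 0.054). Without a block the log2 fold change of HEY2 was 0.86. VASN did not pass with quantile normalisation (adjusted p = 0.0709), DLX3, MYB, VASN and CD70 did not with a log offset of 1, nor MYB and HEY2 with one of 64, and DLX3, SOCS3, VASN, HEY2, SLC25A25 and GADD45B did not without both replicate 3 arrays.

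The comparison in polysome-associated RNA asks which transcripts change on ribosomes that are actively translating. Of the 18 genes that rose in total RNA, 14 rose here, and MYB, KLF10, HEY2 and CA12 did not pass (adjusted p = 0.298, 0.0996, 0.0857 and 0.132 in limma). KCNK5 went from 93.2 ± 17.6 to 651.3 ± 185 (SD, n = 3), a log2 fold change of 2.58 (SE 0.21, adjusted p = 2.71e-06). MYC rose by 1.67 (SE 0.17), SGK1 by 1.67, FOS by 1.64, SOCS3, an inhibitor of cytokine signalling, by 1.13, and XBP1 by 1.10 (adjusted p = 8.85e-05). RBM24, an RNA-binding protein gene, rose by 1.38 (adjusted p = 0.0015) and CISH, another inhibitor of cytokine signalling, by 0.86. PFKFB3, an enzyme that stimulates glycolysis, rose by 0.79. DLX3, a homeobox gene, rose by 1.25 and VASN, which encodes the membrane protein vasorin, by 1.05, after rises of 1.15 and 0.92 in total RNA. Of the 38 early estrogen-induced genes 7 rose and 0 fell, and adjusted over the list alone 20 rose. Their median in polysomes was 0.46 (camera adjusted p = 3.33e-63, and adjusted p = 2.05e-05 with an estimated correlation).

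The 71 measured mRNAs of ribosomal proteins and elongation factors, whose translation is regulated through their leader sequence, had a median log2 fold change of 0.15 in polysomes. Relative to the all-gene median it was 0.18. In polysomes 0 of these TOP mRNAs passed on their own by limma, 0 passed adjusted over the list alone, and 9 had an unadjusted p under 0.05, all higher. The list was shifted up relative to other genes (camera adjusted p = 3.01e-19, and adjusted p = 0.0129 with an estimated correlation). By fry, which tests against no change, the adjusted p was 0.057. Its median was 0.003 in total RNA and 0.02 in monosomes, and no shift was called there with all arrays, but in total RNA the list was called up without E2 total replicate 1 (median 0.0436, adjusted p = 0.00555), so a shift in polysomes only is not shown. Without E2 polysome replicate 2 the median in polysomes was 0.086.

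Other lists were called in polysomes at the preset correlation only. Among immediate early genes 5 rose (FOS, MYC, SGK1, KLF4 and GADD45B) and 0 fell, against 8 and 1 (TRIB1) adjusted over the list alone, with a median of 0.06 that ran from 0.026 to 0.127 without single arrays (adjusted p = 5.12e-10, and adjusted p = 0.0868 with an estimated correlation). The 16 luminal epithelial markers, of which XBP1 alone rose over all genes and adjusted over the list alone, had a median of 0.06, from 0.021 to 0.160 without single arrays (adjusted p = 0.000747, and adjusted p = 0.0868 with an estimated correlation), a call lost without vehicle polysome replicate 2. Genes of secreted and membrane proteins, of which STC2 alone rose (TFF1 also, adjusted over the list alone), had a median of 0.05 that ran from 0.0033 to 0.101 without single arrays (adjusted p = 0.000103, and adjusted p = 0.186 with an estimated correlation). Replication-dependent histone mRNAs had a median of 0.13, which was 0.0014 without E2 polysome replicate 2 and 0.276 without replicate 3, with 0 members passing by limma and 0 at an unadjusted p under 0.05 (adjusted p = 0.0002, and adjusted p = 0.586 with an estimated correlation). That call was lost without E2 polysome replicate 2 or without vehicle polysome replicate 2. KLF4 was the member of the estrogen-repressed list that rose in polysomes, by 0.79, and adjusted over the list alone HES1, a Notch target, also rose, by 0.52. TFF1 stood at 0.75 (0.50 to 0.92 without single arrays) and EGR3 at 1.25 in polysomes, without passing over all genes (adjusted p = 0.329 and 0.449 by limma), and EGR3 passed adjusted over the immediate early list alone.

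In polysomes limma called 17 genes higher and 0 lower. At an unadjusted p under 0.05 there were 149 higher and 141 lower, and chance gives 921 in all. All 17 were free of overlap between the 3 E2 and 3 vehicle arrays, as were 956 of all genes, against a chance share of 10%. Of 15 named genes that passed, 9 passed whichever single array was left out, and CISH, DLX3, KLF4, PFKFB3, SLC25A25 and VASN did not. Without E2 polysome replicates 1, 2 and 3 the losses among these were 6, 5 and 2, and without vehicle polysome replicates 1, 2 and 3 they were 5, 4 and 1. The whole count was 9, 10 and 14 without E2 polysome replicates 1, 2 and 3, and 11, 13 and 15 without vehicle polysome replicates 1, 2 and 3. With array weights it was 100, with 75 higher and 25 lower. With quantile normalisation VASN, CISH and SLC25A25 did not pass in polysomes (adjusted p = 0.0514, 0.138 and 0.1), nor did VASN and CISH with a log offset of 1, or CISH with one of 64 or without both replicate 3 arrays of total RNA.

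The comparison in monosome-associated RNA asks the same of transcripts in the single-ribosome fraction. KCNK5 rose from 59.9 ± 9.51 to 346.2 ± 70.5 (SD, n = 3), a log2 fold change of 2.24 (SE 0.21, adjusted p = 2.86e-05). SGK1 rose by 1.46, CA12, a membrane carbonic anhydrase, by 1.36 (SE 0.14, adjusted p = 7.83e-05), RBM24 by 1.32, MYC by 1.30 and STC2 by 1.22. CXCL12, a chemokine and known estrogen target, rose by 1.28 (SE 0.19, adjusted p = 0.00248). MSMB, which encodes a secreted microseminoprotein, rose by 1.01, and P2RY2, a receptor for extracellular nucleotides, by 0.83. ZNF552, a zinc finger gene, rose by 1.14 and IL12A, an interleukin subunit gene, by 1.01. RAB44, a member of the Rab GTPase family, fell by 1.48 on the log2 scale (SE 0.16, adjusted p = 0.000133), from 233.5 ± 42.3 to 73.6 ± 15.1 (SD, n = 3), while its other probe set stood at 0.13 (unadjusted p = 0.588).

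Of the 38 early estrogen-induced genes 9 rose in monosomes and 0 fell, and adjusted over the list alone 21 rose. Their median in monosomes was 0.57 (camera adjusted p = 1.53e-49, and adjusted p = 7.42e-05 with an estimated correlation). Among immediate early genes FOS, MYC and SGK1 rose. Adjusted over the list alone 7 rose, EGR3 among them, and 1 fell, CCN2, a matrix-associated growth regulator. For the immediate early list the median in monosomes was -0.03 (-0.11 to 0.11 without single arrays), the mean 0.11 and the direction of the test up, and no shift was called (adjusted p = 0.156). None of the 27 genes reported as estrogen-repressed passed by limma, 5 had an unadjusted p under 0.05 (2 higher and 3 lower), and adjusted over the list alone KLF4 rose by 0.48 and 3 fell, EFNA1, VTCN1 and PIK3IP1. Small noncoding RNA genes had a median of 0.15, with 0 of 211 passing by limma and 23 higher and 0 lower at an unadjusted p under 0.05 (adjusted p = 5.81e-07, and adjusted p = 0.496 with an estimated correlation). Ribosome biogenesis factors had a median of 0.13 with 0 passing by limma, 3 at an unadjusted p under 0.05 and 1 higher adjusted over the list alone, NOP16 (adjusted p = 0.00037, and adjusted p = 0.496 with an estimated correlation). Genes of secreted and membrane proteins had a median of 0.05, with STC2 passing and IGFBP4 also higher adjusted over the list alone (adjusted p = 0.00692, and adjusted p = 0.496 with an estimated correlation). Histone mRNAs had a median of -0.08, with 0 passing by limma and 5 lower at an unadjusted p under 0.05 (adjusted p = 0.00692, and adjusted p = 0.743 with an estimated correlation). The preset calls of these 4 lists were lost without single arrays. For the small noncoding RNAs this was E2 monosome replicate 3 (median 0.074, against 0.238 without vehicle monosome replicate 1). For ribosome biogenesis it was E2 monosome replicate 3 (0.080) or vehicle monosome replicate 1 (0.059). For secreted and membrane proteins it was E2 monosome replicate 1 or 2 or vehicle monosome replicate 1 (0.021, against 0.11 without E2 monosome replicate 3), and for histones E2 monosome replicate 2 or vehicle monosome replicate 1 (median 0.033).

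In monosomes limma called 20 genes higher and 1 lower, with 506 higher and 250 lower at an unadjusted p under 0.05, where chance gives 921 in all. All 21 were free of overlap between the 3 E2 and 3 vehicle arrays, as were 1495 of all genes, against a chance share of 10%. Of 17 named genes that passed, 11 passed whichever single array was left out, and FOS, IL12A, SLC25A25, SOCS3, XBP1 and ZNF552 did not. Without E2 monosome replicates 1, 2 and 3 the losses among these were 6, 3 and 2, and without vehicle monosome replicates 1, 2 and 3 they were 3, 3 and 2. The whole count was 14 to 27 without single arrays, with 14 without E2 monosome replicate 1 and 27 without vehicle monosome replicate 2. It was 9 with only these 6 arrays in the fit and 41 with array weights. XBP1, which rose by 0.66 in monosomes, did not pass with the replicate number as a block (adjusted p = 0.053), with quantile normalisation (0.0876) or with each array centred on its median (0.0526), and SOCS3, ZNF552 and IL12A did not with a log offset of 1.

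With all arrays and genes and the values as deposited, camera at the preset correlation called no list other than those named above in the 3 comparisons of E2 with vehicle, and fry called only the early estrogen-induced genes. The lists not called include REST target genes, REST and its corepressors, initiation factors, mRNAs with regulatory upstream reading frames, G1/S and S phase genes, heat shock genes, long noncoding RNAs and markers of other cell types. REST targets were called at the preset correlation without vehicle total replicate 2 in total RNA (median -0.046, adjusted p = 0.0253) and without vehicle monosome replicate 2 or 3 in monosomes (medians -0.027 and -0.071, adjusted p = 0.0299 and 0.0337). Histone mRNAs were called lower in total RNA with quantile normalisation (median -0.094, adjusted p = 0.0213), without the dimmest 50% of genes (adjusted p = 0.00537), with a log offset of 64 and without both replicate 3 arrays, ribosome biogenesis factors were called there with an offset of 64, and estrogen-repressed genes were called in monosomes without the dimmest 50% (adjusted p = 0.0219). Leaving out 1 array also added calls of ribosome biogenesis, histone and small noncoding RNA genes in total RNA, of small noncoding RNAs in polysomes and of immediate early genes in monosomes. For each list from REST targets to markers of other cell types the count of members that passed by limma was 0 in each fraction. At an unadjusted p under 0.05, REST targets numbered 3, 0 and 3 in total, polysome and monosome RNA. REST with its corepressors and the initiation factors numbered 0 in each fraction, mRNAs with upstream reading frames 1, 1 and 0, and G1/S and S phase genes 1, 2 and 1. Heat shock genes numbered 0, 1 and 0, long noncoding RNAs 0, 2 and 0, and markers of other cell types 0, 0 and 2. Adjusted over the list alone, the count of each of these lists was 0. REST itself stood at -0.18 in polysomes (95% confidence interval -0.68 to 0.31) and at -0.05 in monosomes (-0.55 to 0.44), and without single arrays these values ran from -0.31 to -0.06 and from -0.21 to 0.06.

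The E2 responses of the 3 fractions were then set side by side. KCNK5, MYC, SGK1, FOS, TIPARP, STC2, SOCS3, XBP1 and SLC25A25, which encodes a mitochondrial carrier, passed in all 3, though with quantile normalisation SLC25A25 did not pass in polysomes (adjusted p = 0.1) or XBP1 in monosomes (0.0876). In all, 32 genes passed in at least 1 fraction, 16 in at least 2 and 9 in all 3. Of the 32, 29 had positive estimates in each fraction. Over all genes the E2 effects correlated at 0.06 between total and polysome RNA. The correlation was 0.225 between total and monosome RNA and 0.167 between polysome and monosome RNA. Rank correlations were -0.079, 0.18 and 0.069 in the same order, so broad agreement outside the genes that passed is not shown. Total and polysome RNA shared 14 genes, where independent lists would share 0.0166. Total and monosome RNA shared 10 against 0.0196, and polysome and monosome RNA shared 10 against 0.0185. The fractions share no arrays, but per the labels polysome and total RNA came from the same cells. Deviations of same-numbered arrays of these 2 fractions correlated at 0.118, 0.196 and 0.475 in vehicle cells and at 0.014, 0.024 and -0.186 in E2 cells. Vehicle polysome arrays also correlated with same-numbered E2 total arrays, from other cultures, at -0.036, 0.186 and 0.576. The sharing in vehicle cells is therefore not shown to come from the culture.

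**Figure D2:**
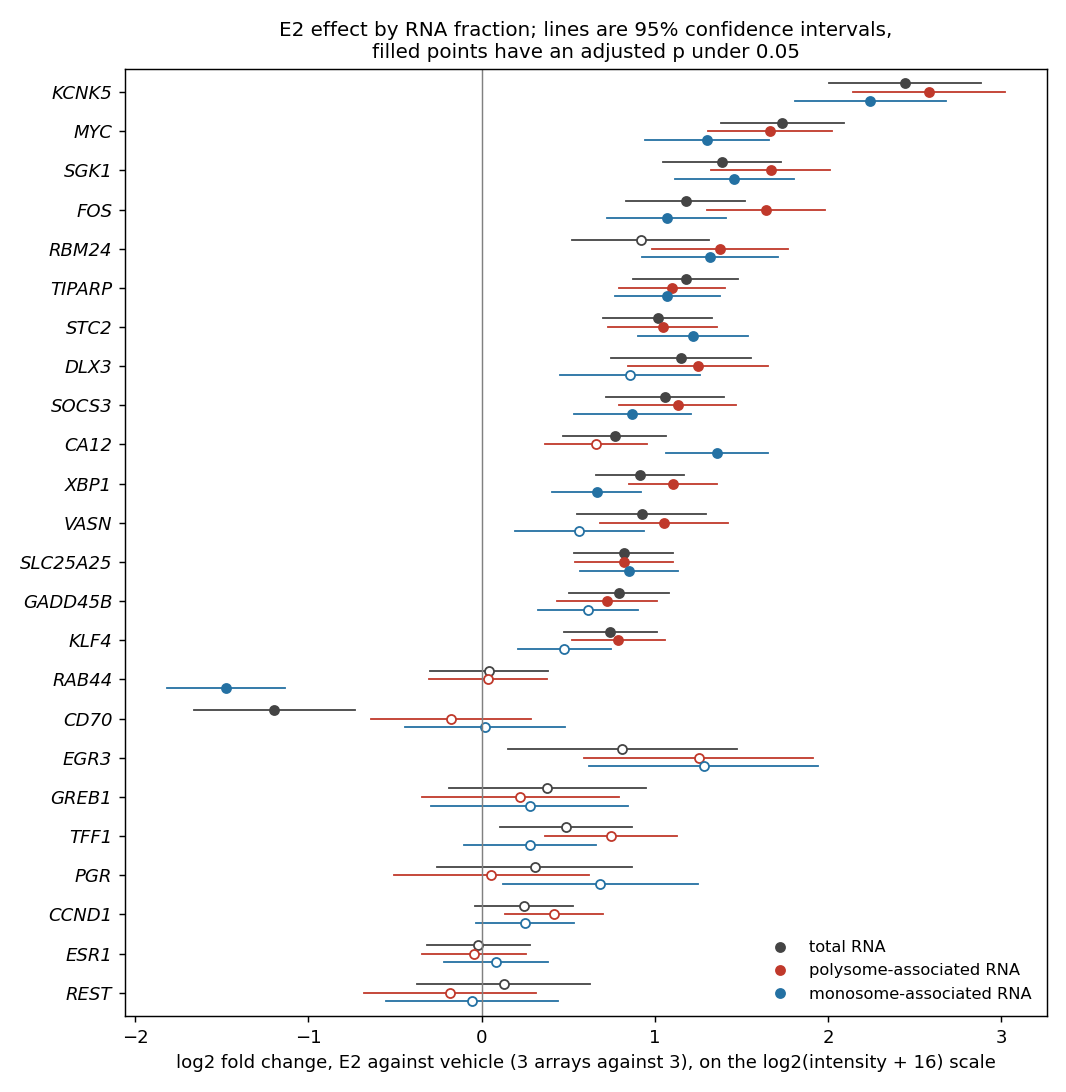
E2 effect (log2 fold change of intensity + 16, horizontal axis) of named genes in total, polysome and monosome RNA, as points with 95% confidence intervals, filled where the adjusted p was under 0.05. KCNK5 lies at 2.44, 2.58 and 2.24, and RAB44 at 0.04, 0.04 and -1.48.

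Whether E2 acts differently on ribosome-bound and on total RNA was tested as the difference between the E2 effects. RAB44 was the gene that passed, by 1 of its 2 probe sets. Its E2 effect in monosomes was lower than in total RNA by a log2 difference of -1.52 (SE 0.23, adjusted p = 0.0452) and its effect in polysomes exceeded that in monosomes by 1.52 (adjusted p = 0.0475). The dimmer probe set of RAB44 had differences of -0.31 and -0.16 (unadjusted p = 0.382 and 0.653) and an E2 effect of 0.13 in monosomes, so it does not support the call. Without single arrays the difference of the brighter probe set ranged from -1.67 to -1.39 in monosome against total RNA and from 1.38 to 1.64 in polysome against monosome RNA. The RAB44 call was lost without 8 of the 12 arrays for the former and 10 of the 12 for the latter, with adjusted p up to 0.259, and it was kept only without E2 total replicate 3, vehicle total replicate 1, E2 monosome replicate 2 or vehicle monosome replicate 3 for the former, and without E2 monosome replicate 2 or vehicle monosome replicate 3 for the latter. The call was also lost with a block for each culture (adjusted p = 0.0928 and 0.0968), with trend and robust options (0.0535 and 0.0562), with log offsets of 1 and 64, with only the compared groups in the fit and with every probe set tested, and RAB44 was not among the genes tested without the dimmest 50%. The E2 effect in polysomes against total RNA had 0 genes passing by limma, and 90 with array weights. At an unadjusted p under 0.05 in limma there were 306, where chance alone gives 921. The smallest adjusted p was 0.999. Among the genes with the smallest p there, FCER1G, an immunoglobulin receptor subunit, had a difference of 0.93, FOXN1 0.74 and ZNF683 0.60. CRISPLD1 had a difference of -0.71 and TPH2, a serotonin synthesis enzyme, of -0.72. Group mean intensities were near the offset of 16 for FCER1G (15.6 to 45.1), CRISPLD1 (11.4 to 33.7) and TPH2 (8.41 to 20.9).

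CXCL12 had an E2 effect of 0.35 in total (0.18 to 0.49 without single arrays) and 0.33 in polysome RNA against 1.28 in monosomes. The difference from total RNA was 0.93 (95% confidence interval 0.38 to 1.48, unadjusted p = 0.00214 in limma), and it did not pass. Among the early estrogen-induced genes, CXCL12 at -0.95 and CA12 at -0.70 passed for polysome against monosome RNA when adjusted over the list alone, and 0 of the 38 passed over all genes by limma, with 4 at an unadjusted p under 0.05. Against total RNA, CA12 had a difference of 0.59 (0.18 to 1.01) and MSMB one of 0.71 (0.33 to 1.09), neither passing. CD70, at -0.18 in polysomes and 0.02 in monosomes, had differences from total RNA of 1.02 and 1.22 that did not pass. After RAB44, the smallest p in monosome against total RNA belonged to ENPP6 at 1.27 (adjusted p = 0.946). In polysome against monosome RNA OR1D5, an olfactory receptor, stood at 1.20 and ST8SIA2, a sialyltransferase, at -1.05. ST8SIA2 passed only without vehicle monosome replicate 3 (-1.38, adjusted p = 0.024). Group mean intensities were 13.5 to 32.8 for ENPP6 and 8.52 to 25.2 for OR1D5, near the offset of 16. The interval for MYC in polysome against total RNA was -0.58 to 0.43, and that for KCNK5 -0.48 to 0.76.

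The comparison of polysome with total RNA asks which transcripts are carried by several ribosomes, whatever the treatment. Noncoding RNAs and ribosomal protein mRNAs were low in polysomes. Values here are log2 differences less the all-gene median of 0.08. RMRP, the RNA of a ribonuclease that processes ribosomal RNA, stood at -4.84 (SE 0.23, adjusted p = 3.43e-11). RPPH1, the RNA of ribonuclease P, stood at -4.34 and TERC, the telomerase RNA, at -3.21. The small nucleolar RNAs SNORD57 and SNORD33 stood at -5.62 and -5.28. FTL, the ferritin light chain mRNA, whose translation is controlled by iron, stood at -2.24 (SE 0.13). FTH1P5, a ferritin heavy chain pseudogene, stood at -1.97. At the other end, HINT3, a nucleotide hydrolase gene, stood at 1.90 (SE 0.13), BLOC1S6, which serves lysosome-related organelles, at 1.89, PIK3C2A, a lipid kinase gene, at 1.74 and NDUFA5, of respiratory complex I, at 1.73.

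Of the 71 TOP mRNAs, 64 were lower and 0 higher in polysomes than in total RNA, and adjusted over the list alone 64 were lower and 2 higher. Relative to all genes their median was -0.88 (adjusted p = 0.00191 with an estimated correlation), and RPS19 stood at -1.79 and RPS29 at -1.78. The raw median of this list lay between -1.07 and -0.70 under 4 other scalings. Of 211 small noncoding RNAs 135 were lower and 0 higher, with 136 lower adjusted over the list alone and a relative median of -0.91 (adjusted p = 0.00561 with an estimated correlation). Of 8 long noncoding RNAs 5 were lower and 2 higher, the same adjusted over the list alone, with a relative median of -1.03 (adjusted p = 0.0104 with an estimated correlation). REST targets had 13 lower and 4 higher, against 11 and 3 adjusted over the list alone, with a relative median of -0.18 (adjusted p = 0.000874, and adjusted p = 0.0855 with an estimated correlation). Among them CHGA, a granin of secretory granules, stood at -0.85 and GDAP1 at 0.82. Markers of other cell types had 4 lower and 1 higher, against 3 and 1 adjusted over the list alone (adjusted p = 0.0208, and adjusted p = 0.408 with an estimated correlation), and their raw median of -0.08 (-0.13 to -0.05 without single arrays) turned positive with quantile normalisation or with centring of each array. FN1, fibronectin, was the largest among these at -1.50.

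Camera called no shift for the other lists in polysome against total RNA as deposited, and fry called each of them up except the immediate early genes. That list was called lower by camera with quantile normalisation (median -0.122, adjusted p = 0.00774), with quantile normalisation of the tested genes (-0.231, adjusted p = 0.00652) and without the dimmest 50% of genes. Estrogen-repressed genes were called up without both replicate 3 arrays of total RNA or without E2 total replicate 3, and upstream reading frame mRNAs without both. Initiation factors had 21 members higher and 6 lower, and EIF3J stood at 1.06. Early estrogen-induced genes had 17 higher and 2 lower, estrogen-repressed genes 13 and 1, ribosome biogenesis factors 18 and 9, G1/S and S phase genes 15 and 7, and mRNAs with upstream reading frames 9 and 0. These counts adjusted over the list alone were 22 and 7, 17 and 3, 13 and 1, 19 and 9, 15 and 7, and 9 and 0. Secreted and membrane protein genes had 17 higher and 5 lower, histones 14 and 2, heat shock genes 8 and 1, luminal markers 7 and 2, REST with its corepressors 7 and 1, and immediate early genes 6 and 8. When adjusted over the list alone they were 17 and 5, 11 and 2, 8 and 1, 7 and 2, 7 and 1, and 5 and 8. The sign of the median of each list in this last group turned under at least 1 other scaling, as did that of the estrogen-repressed genes. REST mRNA stood at 0.78 (SE 0.17, adjusted p = 0.000306).

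Limma called 5874 genes higher and 2507 lower in polysomes, with 1010 and 184 changed at least 2-fold. This split rests on the scaling. Higher against lower was 7176 to 1541 with each array centred on its median, 4201 to 4135 with quantile normalisation of the tested genes and 4421 to 5155 with centring on the tested genes. The all-gene median was 0.08 as deposited and 0.17, -0.04 and -0.08 under these scalings. In E2 cells alone 4983 genes passed.

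The comparison of monosome with total RNA asks which transcripts are enriched in the single-ribosome fraction. The 12 named genes with the highest values included 5 zinc finger (ZNF) genes. ZNF91, a zinc finger gene that represses transposable elements, stood at 3.02 (SE 0.18, adjusted p = 3.95e-11) and ZNF117 at 2.87. RSRP1 stood at 2.49, TAF1D, a subunit of an RNA polymerase I factor, at 2.33 and WSB1 at 2.27. PLEC, which encodes the linker protein plectin, stood at -3.87 (SE 0.13, adjusted p = 1.22e-13). TLN1, the focal adhesion protein talin, stood at -2.96, MYH14, a non-muscle myosin heavy chain, at -2.94, NOTCH2, a signalling receptor, at -2.85, PRKDC, a DNA repair kinase, at -2.74 and AHNAK, a scaffold protein, at -2.69.

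Of the 71 TOP mRNAs 59 were higher and 0 lower in monosomes, against 63 and 0 adjusted over the list alone, with a median of 0.48 (camera adjusted p = 1.03e-16, and adjusted p = 0.0218 with an estimated correlation). RPL26 stood at 2.11, RPL22 at 1.98 and HNRNPA1 at 1.86. Of 56 secreted and membrane protein mRNAs 51 were lower and 1 higher in monosomes, the same adjusted over the list alone, with a median of -1.29 (camera adjusted p = 1.28e-18, and adjusted p = 0.0103 with an estimated correlation). IGFBP5, a binding protein of insulin-like growth factors, stood at -2.62, GRN, progranulin, at -2.51 and CELSR2, a cadherin, at -2.36. Both directions held under 4 other scalings, with medians of 0.37 to 0.56 and of -1.34 to -1.05.

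At the preset correlation alone, 7 further lists were called in monosome against total RNA. Histone mRNAs had 32 lower and 1 higher, with H1-2 at -1.36 and a median of -0.67 (adjusted p = 8.28e-05, and adjusted p = 0.408 with an estimated correlation). Luminal markers had 11 lower and 0 higher, with the receptor gene ERBB3 at -1.99 and CDH1, which encodes E-cadherin, at -1.50 (adjusted p = 0.00106, and adjusted p = 0.0848 with an estimated correlation). G1/S and S phase genes had 23 lower and 4 higher, with TK1, thymidine kinase, at -1.85 (adjusted p = 0.00414, and adjusted p = 0.425 with an estimated correlation). REST with its corepressors had 12 lower and 2 higher, with the chromatin remodeller SMARCA4 at -1.39 and REST at -1.03 (adjusted p = 0.00677, and adjusted p = 0.408 with an estimated correlation). Heat shock genes had 10 lower and 3 higher, with the chaperone gene HSPA5 at -1.87 (adjusted p = 0.0154, and adjusted p = 0.408 with an estimated correlation). Early estrogen-induced genes had 19 lower and 7 higher, with the transporter gene ABCA3 at -2.01 (adjusted p = 0.0158, and adjusted p = 0.408 with an estimated correlation). Long noncoding RNAs had 4 higher and 0 lower, among them JPX at 1.72 and MALAT1 at 0.65 (adjusted p = 0.0154, and adjusted p = 0.0848 with an estimated correlation). Adjusted over the list alone, 33 histones were lower and 1 higher and 11 heat shock genes lower and 3 higher, and the other counts of this group were unchanged.

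Camera called no shift in monosomes, as deposited and with all arrays, for initiation factors (10 higher and 20 lower, with the kinase gene MTOR at -1.71), ribosome biogenesis factors (11 and 22), immediate early genes (6 and 18), estrogen-repressed genes (6 and 12), REST targets (15 and 7) or markers of other cell types (4 and 3). REST targets adjusted over the list alone numbered 14 and 7, and the others had the same counts. Of these, fry called initiation factors, ribosome biogenesis factors, immediate early genes and estrogen-repressed genes lower. With the replicate number as a block the ribosome biogenesis list was called by camera (adjusted p = 0.0497), as it was with centring on the tested genes (0.0443) and without 5 of the 12 single arrays. Upstream reading frame mRNAs had 6 higher and 6 lower and a median of -0.08 that was -0.02 without E2 total replicate 3 and turned positive with quantile normalisation. DDIT3, a stress-response transcription factor on this list, stood at 0.64 (adjusted p = 0.0206), a call lost without E2 total replicate 1 or without vehicle monosome replicate 2. Small noncoding RNAs had 54 higher and 36 lower, against 51 and 34 adjusted over the list alone, and a median of 0.04 (0.027 to 0.070 without single arrays) that turned negative with each array centred on its median, and they were called without 7 of the 12 single arrays (lowest adjusted p = 0.0259) or without both replicate 3 arrays of total RNA (0.0299).

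Limma called 4248 genes higher and 5564 lower in monosomes than in total RNA, with 492 and 1611 changed at least 2-fold. Centring on the tested genes gave 5755 higher and 5004 lower.

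**Figure D3:**
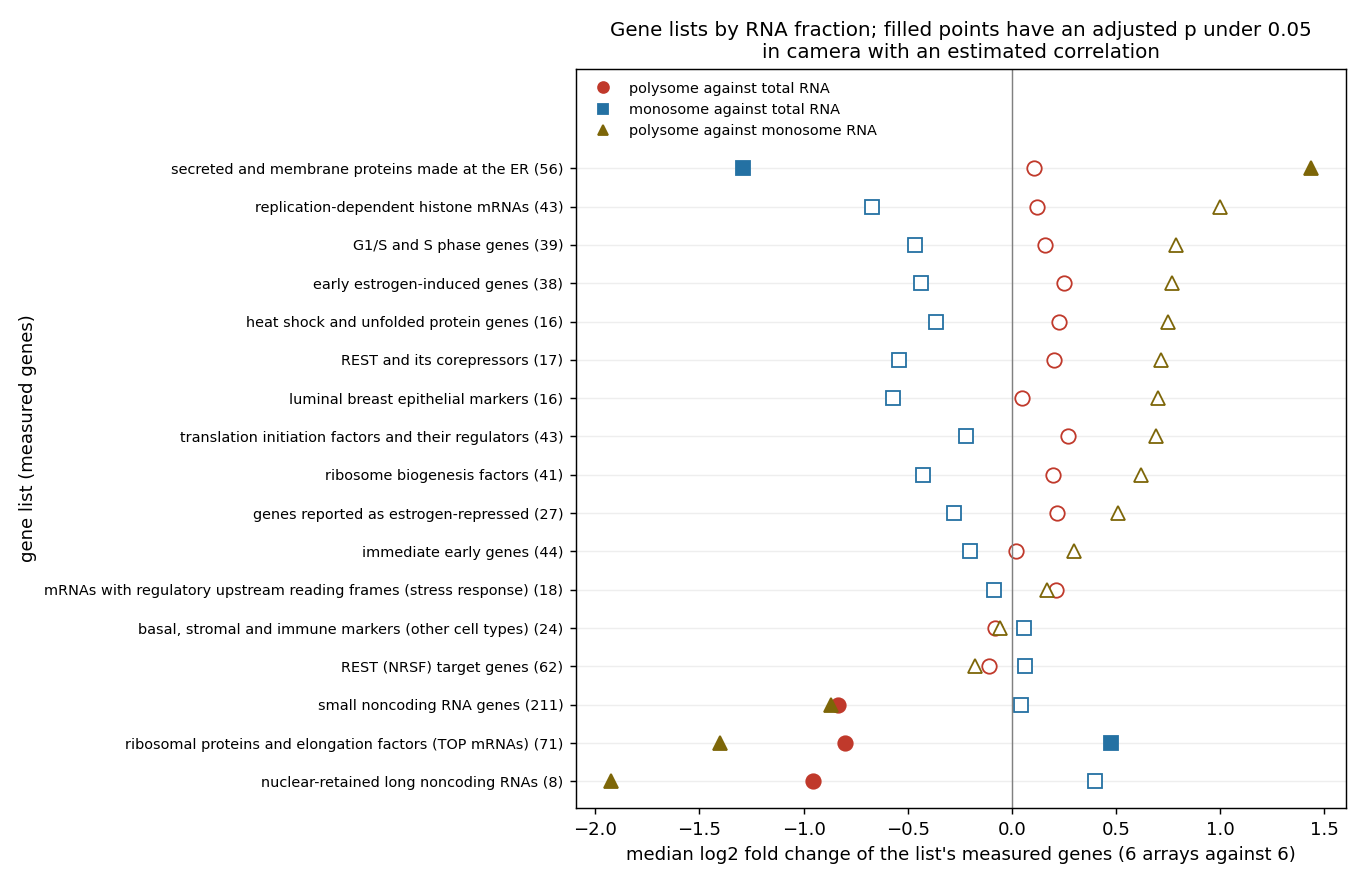
Median log2 fold change of each gene list (horizontal axis, as deposited) in the 3 comparisons of fractions, filled where camera with an estimated correlation gave an adjusted p under 0.05. TOP mRNAs lie at -0.80, 0.48 and -1.40 for polysome against total, monosome against total and polysome against monosome RNA, and secreted and membrane protein mRNAs at -1.29 in monosome against total RNA; these signs hold under 4 other scalings.

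The direct comparison of polysome with monosome RNA asks how transcripts divide between these fractions. Untranslated RNAs are among its largest values, so a value does not by itself show how many ribosomes a transcript carries. Values here are log2 differences less the all-gene median of 0.14. APOD, an apolipoprotein, stood at 2.94 (SE 0.14, adjusted p = 6.49e-13), TSPAN3, a tetraspanin, at 2.70, CPE, a prohormone-processing carboxypeptidase, at 2.65, IGFBP5 at 2.62 and CTSL, a lysosomal protease, at 2.49. PLEC stood at 2.55. RMRP stood at -4.84, RPPH1 at -4.48, TERC at -3.60, RPS29 at -3.51 and RPL26 at -3.21.

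Secreted and membrane protein mRNAs had 52 of 56 higher and 1 lower in polysomes than in monosomes, the same adjusted over the list alone, with a relative median of 1.30 (adjusted p = 0.0158 with an estimated correlation). NOTCH2 stood at 2.47 and PTPRF, a receptor phosphatase, at 2.30. Of 71 TOP mRNAs 70 were lower and 0 higher, the same adjusted over the list alone, with a relative median of -1.54 (adjusted p = 0.0021 with an estimated correlation). The raw medians of these lists kept their signs under 4 other scalings, at 0.87 to 1.58 and -1.66 to -1.26. Of 211 small noncoding RNAs 146 were lower and 2 higher (median -0.87 before the all-gene median was taken off, adjusted p = 0.0158 with an estimated correlation). Of 8 nuclear-retained long noncoding RNAs 7 were lower and 1 higher (relative median -2.06, adjusted p = 0.00756 with an estimated correlation), and both counts were the same adjusted over the list alone.

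Further lists were called between polysomes and monosomes at the preset correlation only. Those with most members higher in polysomes were histones (34 higher and 3 lower), G1/S and S phase genes (27 and 4), early estrogen-induced genes (28 and 4), heat shock genes (12 and 0), REST with its corepressors (13 and 0), luminal markers (14 and 1), initiation factors (32 and 8), ribosome biogenesis factors (29 and 5) and estrogen-repressed genes (17 and 2). With an estimated correlation the adjusted p was 0.31 for the histone and S phase lists, 0.116 for the luminal list, 0.361 for ribosome biogenesis and 0.288 for the other 5. Adjusted over the list alone the S phase count was 28 and 4, that of REST with its corepressors 13 and 1 and that of estrogen-repressed genes 18 and 2, with the rest unchanged. PCNA, the sliding clamp of DNA replication, stood at 2.01, ERBB3 at 2.08, ESR1 at 1.25 and REST at 1.75 (SE 0.17). REST targets had 28 lower and 7 higher, against 27 and 7 adjusted over the list alone (adjusted p = 0.0019, and adjusted p = 0.103 with an estimated correlation). Among these REST targets CPLX1, a synaptic vesicle protein, stood at -1.29 and KIF1A, a kinesin, at 1.48. Markers of other cell types had 8 lower and 5 higher (adjusted p = 0.0313, and adjusted p = 0.288 with an estimated correlation), the same adjusted over the list alone, and their raw median of -0.06 (-0.09 to -0.03 without single arrays) turned positive with quantile normalisation or with centring of each array. Immediate early genes (24 higher and 11 lower) and upstream reading frame mRNAs (8 and 4, and 8 and 3 adjusted over the list alone) were not called by camera but were called up by fry, and the raw median of both turned negative with quantile normalisation of the tested genes. IER3 and ZFP36, immediate early regulators of survival and of mRNA decay, stood at -1.79 and -1.68.

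Limma called 7946 genes higher and 4603 lower in polysomes than in monosomes, with 3213 and 605 changed at least 2-fold. Higher against lower was 9309 to 3298 with each array centred on its median, 5977 to 5943 with quantile normalisation of the tested genes and 6404 to 7520 with centring on the tested genes, and the all-gene median was 0.28, -0.01 and -0.10. Fraction differences in vehicle cells and in E2 cells correlated across genes at 0.918, 0.941 and 0.964 for polysome against total, monosome against total and polysome against monosome RNA.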

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

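The tests of the zinc finger genes and the scalings over the tested genes were chosen after the data were seen, and the rule that a value must clear its bound by 1 standard deviation was added after the TOP result was seen. Results are given here when the E2 effect differed between fractions by a test of the difference itself, or when a signal lay outside the genes that were tested.

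RAB44 had an E2 effect in monosomes lower than that in total RNA by a log2 difference of -1.521 (SE 0.23, adjusted p = 0.0452 in limma). Its effect in polysomes was above that in monosomes by 1.515 (adjusted p = 0.0475). Its other, dimmer probe set had differences of -0.3089 and -0.1574 (unadjusted p = 0.382 and 0.653), so the call rests on 1 of 2 probe sets that disagree. Over the alternatives that leave out 1 array the adjusted p ran from 0.00792 to 0.259 for the former and from 0.024 to 0.259 for the latter. Both calls were lost with a block for each culture (adjusted p = 0.0928 and 0.0968), with trend and robust options (0.0535 and 0.0562), with log offsets of 1 and 64, with only the compared groups in the fit and with every probe set tested; they held with the replicate number as a block (0.0317 and 0.0333). Among 100 drawn splits of the arrays, 17 gave as many genes as the 1 gene of the monosome against total test (highest other split 3), and 14 as many as the 1 gene of the polysome against monosome test (highest other split 2), so chance is not excluded for either count.

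The difference between the E2 effects in polysome and total RNA had a real value of 0 genes by limma, which any split reaches, so the splits do not test it. The highest of the other splits called 1814 genes, which points to a structure of the samples. That split moved arrays between treatments within each fraction, and in both fractions it divided the arrays by their value on principal component 2. Polysome arrays lay at 9.79 to 15.2 on one side and at 26.4 to 36.9 on the other. Total RNA arrays lay at -30.3 to -14.9 and at -56.1 to -32.4, with both replicate 3 arrays on the latter side. Whether this component or these arrays account for the 1814 genes was not tested.

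TOP mRNAs (ribosomal proteins and elongation factors) differed in their E2 effect between polysome and total RNA by a median of 0.1322 (adjusted p = 9.76e-08, and adjusted p = 0.408 with an estimated correlation). Between polysome and monosome RNA they differed by 0.1367 (adjusted p = 2.49e-09, and adjusted p = 0.252 with an estimated correlation). Without E2 polysome replicate 2 these differences were 0.0862 and 0.0802.

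Within polysomes alone the median E2 effect of the 71 TOP mRNAs was 0.153. Array scaling that acts by level is argued against, since this median lay at percentile 100 of 10000 random lists matched on mean level, whose highest was 0.0836. Gradients of E2 cells collected at a slightly different place might move mRNAs with a similar division between polysomes and monosomes alike. Lists of genes above the median level, matched on that ratio, put the TOP median at percentile 100 as well, with a highest of 0.0804. This test cannot decide the place of the cut, because the ratio does not give the number of ribosomes on an mRNA. Lists drawn gene by gene also leave out that TOP mRNAs may move together, since another split of the polysome arrays gave 0.174. Dependence on 1 array stays open, since the median was 0.0859 without E2 polysome replicate 2, as does chance, since 2 of 10 splits of the 6 polysome arrays gave a median as far from 0 (highest other 0.174) and a share under 0.05 cannot be reached. A regulated rise of these mRNAs on polysomes may therefore be stated as a hypothesis only.

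Histone mRNAs differed in their E2 effect between polysome and total RNA by a median of 0.2034 (adjusted p = 7.82e-05, and adjusted p = 0.931 with an estimated correlation); without E2 polysome replicate 2 the median was 0.087, and the call was lost there and without E2 total replicate 1 or vehicle polysome replicate 2. Between polysome and monosome RNA histone mRNAs differed by 0.1831 (adjusted p = 5.87e-07, and adjusted p = 0.661 with an estimated correlation), and by 0.027 without E2 polysome replicate 2. Small noncoding RNAs differed between monosome and total RNA by 0.1699 (adjusted p = 0.000829, and adjusted p = 0.941 with an estimated correlation), a call lost without E2 total replicate 1, E2 monosome replicate 3 (0.073) or vehicle monosome replicate 2. They differed between polysome and monosome RNA by -0.1601 (adjusted p = 0.000264, and adjusted p = 0.661 with an estimated correlation), a call lost without vehicle polysome replicate 2 (-0.071), E2 monosome replicate 3 or vehicle monosome replicate 2. Immediate early genes differed between polysome and monosome RNA by 0.08602 (adjusted p = 0.000794, and adjusted p = 0.661 with an estimated correlation), and by 0.017 without E2 monosome replicate 3, where the call was lost. Ribosome biogenesis factors differed between polysome and monosome RNA by -0.1752 (adjusted p = 0.0456, and adjusted p = 0.703 with an estimated correlation), a call lost without 6 single arrays, with -0.092 without vehicle monosome replicate 1, with each array centred on its median and with a log offset of 1. By fry no list was called for these differences. No member of these lists, or of the TOP list, passed on its own by limma in these differences, and between 0 and 12 members of a list had an unadjusted p under 0.05.

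For these differences the number of lists called at the preset correlation was no larger than in many other splits. It was 2 in polysome against total RNA, reached by 88 of 100 splits (highest other 9), 1 in monosome against total RNA, reached by 97 of 100 (highest other 9), and 5 in polysome against monosome RNA, reached by 46 of 100 (highest other 8).

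Probe sets without exactly 1 gene symbol, which were left out of the gene counts, held 2 that passed for E2 in total RNA, 2 in monosome RNA and 1, lower, for the E2 effect in polysome against monosome RNA when every probe set was tested.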

How the results depend on the processing

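Offsets of 1 and 64, the scalings over the tested genes, and the fit without both replicate 3 arrays of total RNA were chosen after the data were seen. The E2 effects of KCNK5, MYC, SGK1 and TIPARP passed in each fraction whichever single array was left out. TOP mRNAs kept their direction in the 3 fraction comparisons under each scaling, and mRNAs of secreted and membrane proteins kept theirs in monosome against total and polysome against monosome RNA, while their median turned in polysome against total RNA. Of 498 results for named genes and lists, 484 stayed on their side of the threshold with quantile normalisation (2 newly passed and 12 no longer did), 495 with each array centred (3 no longer passed), 472 and 496 with the scalings over the tested genes, and 485 and 491 with offsets of 1 and 64. For the results below that changed, the cause was not tested unless it is named. Probe sets near background limit what the arrays show, since up to 21.7% of the probe sets of an array lay below 16 and a change there is compressed by the offset.

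Removing the dimmest 50% of genes left 7699 genes for polysome against monosome RNA, as fewer genes were tested, and 0 for the E2 effect in monosome against total RNA and in polysome against monosome RNA. The count for each of these 2 differences was also 0 with trend and robust options, with log offsets of 1 and 64, with only the compared groups in the fit, and with a culture replicate block. Testing every probe set gave 0 for the E2 effect in monosome against total RNA, 1 in polysome against monosome RNA that is not RAB44 and is lower, and 13170 and 19977 for polysome against total and polysome against monosome RNA, as more features were tested. Array weights gave 799 (369 higher and 430 lower), 100 and 41 genes for E2 in total, polysome and monosome RNA, 90 for the E2 effect in polysome against total RNA and 4 in monosome against total RNA. The weights ran from 0.244 for E2 total replicate 3 to 6.77 for E2 total replicate 2, so 1 array carries most of its group. With only the compared groups in the fit, E2 called 3 genes in total and 9 in monosome RNA, where fewer arrays estimate the spread. The full fit also pools spreads that differed, with median gene standard deviations of 0.21 in E2 total and 0.13 in E2 polysome RNA. Whether the pooling or the number of arrays accounts for the lower counts was not tested. An adjusted p under 0.10 gave 32 for E2 in monosomes, as a looser threshold. Requiring at least a 1.5-fold change gave 3838, 5104 and 7901 in polysome against total, monosome against total and polysome against monosome RNA, as a stricter threshold. In E2 cells only, polysome against total RNA called 4983, from fewer arrays. Without both replicate 3 arrays of total RNA, E2 called 11 in total RNA. Of 51 list calls out of 153, 13 held with an estimated correlation, and fry called 49, of which 32 were shared.

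Leaving out single arrays gave 6 to 19, 9 to 15 and 14 to 27 genes for E2 in total, polysome and monosome RNA. For the E2 effect in polysome against total, monosome against total and polysome against monosome RNA it gave 0, 0 to 1 and 0 to 2. For polysome against total, monosome against total and polysome against monosome RNA it gave 7562 to 8445, 9257 to 9661 and 11980 to 12440, and 47 to 54 list calls. Among tests called in either fit, the direction of 1 reversed: the E2 effect on small noncoding RNAs in polysome against total RNA was -0.086 without E2 total replicate 1 (adjusted p = 0.0384), within a range of -0.087 to 0.054. Medians of other lists changed sign without a turn of a called test, such as that of immediate early genes in total RNA (-0.045 without E2 total replicate 3).

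With the replicate block the counts were 19, 18 and 20 for E2 in total, polysome and monosome RNA, 0, 1 and 1 for the differences between E2 effects, and 8573, 10008 and 12731 for the fraction comparisons. The block ended the calls of HEY2 and CD70 in total RNA (adjusted p = 0.057 and 0.054) and of XBP1 in monosomes (0.053), added that of ribosome biogenesis in monosome against total RNA, and changed no other call among named genes and lists. In polysomes same-numbered E2 and vehicle arrays correlated at 0.024, -0.155 and -0.062, which shows no pairing by number. Culture as a random block gave 19, 17 and 21.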

Other observations

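The families below were chosen after the data were seen, from 53 symbol prefixes, 44 of which held 15 to 3000 genes, and their p values were adjusted over 450 tests; the splits of the arrays were planned.

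Of 47 genes of the proteasome, 33 were lower and 3 higher in monosomes than in total RNA, with a median of -0.57, and 39 were higher and 2 lower in polysomes than in monosomes. Genes of respiratory complex I gave 25 lower and 3 higher of 34 in monosomes, with a median of -0.59, and 30 higher and 1 lower in polysomes against monosomes. Protocadherin genes, which encode adhesion proteins of neurons and epithelia, gave 30 lower and 3 higher in monosomes, with a median of -0.86, and 32 higher and 5 lower in polysomes against monosomes. These signs held under 4 other scalings. Mitochondrial ribosomal protein genes gave 35 lower and 17 higher in monosomes (median -0.26). Olfactory receptor genes, which epithelial cells seldom express, gave 47 higher and 23 lower in monosomes, with a median of 0.04 that turned negative under 2 scalings. With an estimated correlation the adjusted p was 0.993 for each family, so no family shift is called in that test. Zinc finger (ZNF) genes had 283 members higher and 39 lower in polysomes than in total RNA, and 142 and 140 in polysomes against monosomes, where the median of -0.01 turned positive with each array centred on its median.

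The ZNF genes, many of which encode repressors of transposable elements, had 267 members higher and 53 lower of 494 in monosomes than in total RNA, with a median of 0.36. Array scaling that acts by level is argued against, since the monosome median lay at percentile 100 of 10000 lists matched on mean level (highest 0.085), and the lowest median under 4 other scalings was 0.312. The shift was called at the preset correlation (adjusted p = 1.70e-10) and not with an estimated correlation (adjusted p = 0.993, unadjusted 0.121), so the members may move together through a shared cause. The rise over total RNA was not particular to monosomes. In polysomes against total RNA the ZNF median was 0.25 to 0.51 under the 4 other scalings, which a batch of the monosome arrays alone would not give. Cross-hybridisation between these similar genes and any batch that coincides with the fraction were not tested, so the pattern is a hypothesis found and tested on the same data.

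Secreted and membrane protein mRNAs, made on ribosomes bound to the ER, were low in monosomes with a median of -1.29. Array scaling that acts by level is argued against, since this median lay at percentile 0 of 10000 matched lists (lowest -0.703), and scaling between arrays as well, since the value closest to 0 under 4 other scalings was -1.046. Loss of membrane-bound ribosomes from the monosome fraction and a fuller loading of these mRNAs with ribosomes could each give a median of -1.046 or lower. The design does not separate them, and neither was tested. Low monosome values were not confined to this list, since most histone, proteasome and complex I genes were also lower, as was PLEC. The random lists were matched on level only, so other features of the mRNAs, such as length, were not tested. Any hybridisation batch of the monosome arrays cannot be told apart from the fraction, because the labels give none.

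Other splits of the arrays were set against the real ones. With 10 splits of 6 arrays a share under 0.05 cannot be reached. E2 called 19 genes in total RNA, and 1 of the 10 splits, the real one, gave as many (highest other 3). In polysomes E2 called 17, again 1 of 10 (highest other 0), and in monosomes 21, 1 of 10 (highest other 2). Among splits that part as many same-numbered pairs as the real one, the others called 0 genes in total and monosome RNA; those with 1 to 3 genes parted 1 pair. List calls at the preset correlation numbered 3 in total RNA, reached by 8 of 10 splits (highest other 6), 6 in polysomes, reached by 4 of 10 (highest other 8), and 5 in monosomes, reached by 3 of 10 (highest other 6). For the fractions, 8381 genes in polysome against total RNA were reached by 1 of 100 splits (highest other 6527), 9812 in monosome against total RNA by 1 of 100 (highest other 5506) and 12549 in polysome against monosome RNA by 1 of 100 (highest other 8458), so chance can be excluded for these counts. List calls there numbered 5, reached by 40 of 100 splits (highest other 12), 9, reached by 20 of 100 (highest other 15), and 15, reached by 4 of 100 (highest other 15). Chance is not excluded for these list counts, since for the last, although the share is under 0.05, 3 other splits called as many of the 17 lists as the real one.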
